A study of Mus musculus with 30 samples.

How the data were processed

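Bulk RNA-seq was carried out on diaphragm of 15 male mice, with 2 libraries per animal: a perisynaptic piece with neuromuscular junctions and an extrasynaptic piece without them. RNA was extracted with a miRNeasy kit including DNA digestion, and libraries were made with a KAPA stranded mRNA kit. The deposited table holds raw counts per gene, which the authors made with featureCounts on mm10. The aligner, the annotation release and the strand setting of the counting are not given in the sources used here. The table has 33076 genes in 30 libraries, and genes with no count in any library were left out of it before deposition. Gene identifiers were joined to symbols and positions in GENCODE vM21 (GRCm38); 33064 matched and 12 did not, which carried 0.00171% of the counts. Total counts per library ranged from 16280873 to 34694446. Reads without molecular identifiers are not independent molecules, so errors given are those between animals. The exception is the SE of a median over the genes of cell type lists, which is taken over genes.

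Libraries were grouped by genotype, region and age into 8 groups. A fit for each region held the 15 libraries of that region with a mean per genotype and age. From it came SBMA minus control at each age, the difference between these (genotype by age) and the change with age averaged over genotypes. A fit of all 30 libraries had a term for each animal and a region effect for each genotype and age, with 19 columns and 11 residual degrees of freedom. It gave perisynaptic minus extrasynaptic differences in each genotype and the dependence of this difference on genotype at each age. Genes were filtered with filterByExpr (minimum count 10, minimum total 15), which left 15735 perisynaptic, 15526 extrasynaptic and 16138 genes in the joint fit. Counts were scaled with TMM factors and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with no fold minimum. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes tested were called; all tests are 2-sided. Log2 fold changes carry a standard error derived from the fit, and levels are CPM with TMM-scaled library sizes, as mean and SD. A prior count of 2 was used for log2 CPM.

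The groups, comparisons, tests, alternatives, gene lists and the rule for naming genes were chosen before the data were examined. The rule names the 8 largest rises and falls among called genes above 2 CPM in each comparison of genotype or region. It adds up to 4 members of each gene list with the smallest p and, whatever their result, 39 fixed genes. In the other comparisons it names the 5 largest each way and the fixed genes, and a count of 5 or fewer is named in full. The text gives a selection of these genes. The 37 gene lists cover fibre types, sarcomere, synapse, denervation, calcium handling, metabolism, stress responses and markers of cell types. They were tested with camera in limma 3.58.1 at an inter-gene correlation of 0.01, again with an estimated correlation and with fry. Camera compares a list with the other genes, while fry tests whether the genes of a list move on balance one way. Lists were adjusted within each comparison. The text gives a selection of the list results, with values for each call that held with an estimated correlation. Agreement between the ages is a correlation across genes, which are not independent replicates.

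The alternatives were the Wald test of DESeq2 1.42.0, RLE factors, no filter on low counts, each animal left out in turn, replicate number as a block, runs of consecutive animal numbers as a block, and a fit of only the groups compared. For the region fit, a model without the animal term was also run. Scaling by total counts alone was added after the data had been seen. The library names tie the 2 regions of an animal, which is why the animal is a term of that fit. Libraries from the 2 regions of an animal also correlated after group means were removed. This was weakest in SBMA animals at 15 weeks (mean 0.228, lowest 0.0836), where 2 of 4 perisynaptic libraries correlated best with their own animal. The replicate numbers were checked in the same way between SBMA and control animals of one age: in perisynaptic libraries at 26 weeks all 4 same-number pairs correlated above 0.1 (lowest 0.128, mean 0.354). Same-number pairs at this age lie within runs of consecutive animal numbers, and the 8 pairs of one run had a mean of 0.313. A pairing by number therefore cannot be told apart from a difference between the runs. With replicate number as a block 2317 genes were called in place of 2204. In extrasynaptic libraries at 26 weeks 3 of 4 same-number pairs correlated above 0.1, and in neither region at 15 weeks did any. The replicate block is therefore only an alternative. The 26-week animals fall into 2 runs of numbers with 2 SBMA and 2 control animals each. Within the runs, 1107 and 797 perisynaptic and 4023 and 2104 extrasynaptic genes were called. At 15 weeks the runs hold 3 SBMA and 1 control, and 1 SBMA and 2 control animals, so genotype is not balanced over them. Each of these runs has a group of 1 animal, so no count is given. Within each run all genes called at this age kept their direction, though these animals also made the calls. Log2 fold changes within a run correlated with those of all animals with r = 0.71 and 0.734 in perisynaptic and 0.733 and 0.715 in extrasynaptic libraries. The procedure was tested on counts drawn from a negative binomial model, with the mean and dispersion of each gene taken from the data. Known changes were added to 200 genes above 1 CPM, in 1 draw for each comparison, so the shares below do not cover scarcer genes. In the 26-week perisynaptic, 26-week extrasynaptic and control region comparisons 79%, 89% and 99% of 2-fold changes were called. Of the calls 7.25%, 5.97% and 7.87% were false, above the nominal 5%. Runs of animal numbers, outlying libraries and correlation between genes were not simulated, so the real error may differ.

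Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The human transgene was not analysed here. Some genes that the naming rule covers are not reported here.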

Results

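The diaphragm transcriptome was measured in 15 male mice of a model of spinal and bulbar muscular atrophy (SBMA), an inherited disease of motor neurons and muscle. SBMA animals carried BACfxAR121, the transgene that causes the disease in this model. Control animals were littermates with the same transgene and HSA-Cre, a recombinase made in skeletal muscle that rescues this tissue. Each diaphragm gave 2 RNA-seq libraries, one from a perisynaptic piece that held the neuromuscular junctions and one from an extrasynaptic piece without them. There were 4 SBMA and 3 control animals at 15 weeks of age and 4 of each at 26 weeks, so 30 libraries fell into 8 groups by genotype, region and age. Replicates came from separate animals. Total counts per library ranged from 16280873 to 34694446, and 15735 genes were tested in perisynaptic and 15526 in extrasynaptic libraries.

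The comparisons ask which genes differ between SBMA and control muscle near the junctions and away from them, at which age, and whether the difference between the regions is itself altered. Every adjusted p below comes from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and log2 fold changes are given ± SE. All changes are relative to the median gene, which TMM scaling places near 0. With total-count scaling the median gene lay 0.24 above 0 on the log2 scale in perisynaptic and 0.18 in extrasynaptic SBMA libraries at 26 weeks, and 0.19 above 0 in extrasynaptic SBMA libraries at 15 weeks. The 10 most abundant genes took 20.3% ± 1.32 (SD, n = 4) of the counts in perisynaptic control libraries at 26 weeks and 15.4% ± 1.51 (SD, n = 4) in SBMA libraries.

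**Figure D1:**
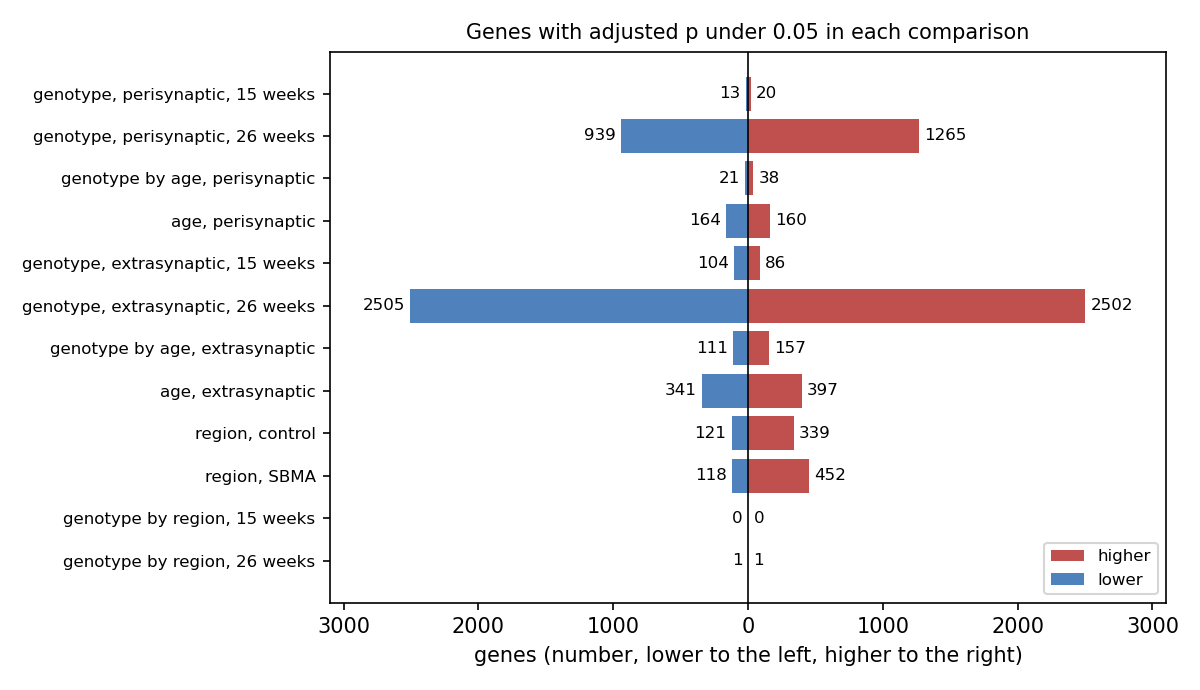
Number of genes with an adjusted p under 0.05 in each of the 12 comparisons (bars, lower to the left and higher to the right; TMM scaling). The SBMA comparison at 26 weeks gave 5007 genes in extrasynaptic and 2204 in perisynaptic libraries, against 190 and 33 at 15 weeks; under total-count scaling the 26-week calls lay mostly on the higher side.

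In perisynaptic muscle of 15-week-old SBMA mice, a small set of transcripts that are scarce in control diaphragm rose and genes of fast muscle fibres were lower as a group. Igsf1, which encodes a membrane glycoprotein of the immunoglobulin superfamily (ENSMUSG00000031111.16, chromosome X, 49782536 to 49797749, GRCm38), rose from 2.35 ± 0.273 CPM (SD, n = 3) to 11 ± 1.11 CPM (SD, n = 4), a log2 fold change of 2.21 ± 0.203 (adjusted p = 0.000202). Prr32 (ENSMUSG00000037086.3), a proline-rich protein gene on the same chromosome (45090904 to 45092791), rose from 0.133 ± 0.0673 to 1.42 ± 0.532 CPM, a log2 fold change of 3.36 ± 0.446. In all, 33 genes passed, 20 higher and 13 lower. Among the other risers were the secretin receptor Sctr (1.49 ± 0.254), Tecrl, an endoplasmic reticulum gene mutated in an inherited cardiac arrhythmia (1.43 ± 0.273), and Tceal7 and Tceal5 (1.29 ± 0.227 and 1.26 ± 0.207). The largest falls among genes above 2 CPM were those of the membrane protease gene Hpn (-1.15 ± 0.207), the secreted signal Wnt4 (-1.01 ± 0.162), Mir133a-1hg, which hosts a muscle microRNA (-0.94 ± 0.153), and the transcriptional repressor Nfil3 (-0.90 ± 0.152). Ptp4a3, a phosphatase, and Coq8a, needed to make coenzyme Q, fell by 0.69 and 0.59.

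None of the 16 fast-fibre genes passed on its own at this age and region, while 12 were lower when adjusted over the list alone, and the list median was -0.50 (camera adjusted p = 1.26e-21, 1e-04 with an estimated correlation). Myh4, the heavy chain of the fastest myosin, stood at -1.24 ± 0.334 (adjusted p = 0.238), the calcium buffer gene Pvalb at -1.17 ± 0.27 (0.13) and the fast calcium pump gene Atp2a1 at -0.72 ± 0.144 (0.0581). Of 64 sarcomere genes none passed, and 10 were lower adjusted over the list alone (median -0.15, camera adjusted p = 1.06e-07, 0.0299 with an estimated correlation). Immediate early genes, which respond to stimulation and to dissection, had a median of -0.51, with 7 of 25 lower adjusted over the list alone (camera adjusted p = 1.82e-11, adjusted p = 0.185 with an estimated correlation). Acetylcholine receptor genes did not pass: Chrna1, the alpha subunit, measured 69.6 ± 16.9 CPM (SD, n = 4) against 50.3 ± 2.91 CPM (SD, n = 3), with a log2 fold change of 0.44 ± 0.165 (adjusted p = 0.526). The count of 33 fell to between 6 and 20 whichever of the 7 animals was left out, and DESeq2 called 129 genes, 49 higher and 80 lower. With replicate number as a block, which leaves fewer residual degrees of freedom, 10 genes passed. Igsf1 and Prr32 alone among the genes named passed without each animal in turn. Sctr, Tecrl, Tceal5, Tceal7, Hpn, Wnt4, Mir133a-1hg, Nfil3, Ptp4a3 and Coq8a each lost the call without most single animals. Their log2 values stayed between 1.08 and 1.53 for the risers and between -0.54 and -1.24 for the fallers.

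In extrasynaptic muscle at 15 weeks the acetylcholine receptor gene Chrna1 was among the 8 largest rises, from 12 ± 1.99 CPM (SD, n = 3) to 33.7 ± 7.29 CPM (SD, n = 4), a log2 fold change of 1.45 ± 0.187 (adjusted p = 0.00114). Chrna1 (ENSMUSG00000027107.3) lies on chromosome 2 (73563215 to 73580338). Colq, which encodes the collagen tail that anchors acetylcholinesterase at the synapse, rose by 1.09 ± 0.213, and Myh8, the perinatal myosin heavy chain, by 0.95 ± 0.191. Igsf1 and Prr32 rose here too, Igsf1 from 2.18 ± 0.33 to 12.7 ± 1.98 CPM. Other rises were those of Rtkn2 (1.85 ± 0.292), the potassium channel gene Kcnj3 (1.67 ± 0.235) and Erc2, a scaffold of presynaptic active zones in neurons (1.66 ± 0.217). In total 190 genes passed, 86 higher and 104 lower. With total-count scaling the count was 2356, of which 95.4% were higher, against 45.3% with TMM factors.

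Falling genes at this age and region were led by Nr4a1, an immediate early nuclear receptor (-1.91 ± 0.376), and Mdga1, a cell-adhesion gene (-1.53 ± 0.217). Next came Pvalb, which went from 1560 ± 156 CPM (SD, n = 3) to 585 ± 82.3 CPM (SD, n = 4; -1.46 ± 0.196). Cacng1, a subunit of the muscle calcium channel (-1.12 ± 0.205), and Atp2a1 (-0.77 ± 0.081) also fell. So did Casq1, the calcium-binding protein of the sarcoplasmic reticulum (-0.46 ± 0.072), Cacna1s, the voltage sensor of the fibre (-0.47 ± 0.096), and the glycolytic gene Aldoa (-0.65 ± 0.101). Of 16 fast-fibre genes 11 were lower over all genes tested and 15 adjusted over the list alone (median -0.58, camera adjusted p = 4.64e-35, 0.0007 with an estimated correlation). Of 64 sarcomere genes 11 were lower and 1 higher, 21 and 1 adjusted over the list alone (median -0.30, camera adjusted p = 8.25e-15, 0.0198 with an estimated correlation). Features like ribosomal RNA also differed between these groups, with 0.304% ± 0.101 (SD, n = 3) of the counts in control and 0.108% ± 0.0728 (SD, n = 4) in SBMA libraries, while in perisynaptic libraries of that age the shares were 0.0584% ± 0.00943 (SD, n = 3) and 0.17% ± 0.0894 (SD, n = 4). Those shares cover 3 features only and are not a total for ribosomal RNA. Gm42418, which is not among these features, took the most counts of any gene in all 3 extrasynaptic control libraries (3.36% to 6.2%) and in SBMA replicate 1 (3.27%). Tpm2, a tropomyosin, stood at -0.75 ± 0.091 and the skeletal actin gene Acta1 at -0.68 ± 0.104. Of 25 synaptic genes Chrna1 and Colq passed and 6 were higher adjusted over the list alone (camera adjusted p = 5.28e-07, adjusted p = 0.0778 with an estimated correlation). The adult receptor subunit gene Chrne measured 1.55 ± 1.93 CPM (SD, n = 4) against 0.37 ± 0.0881 CPM (SD, n = 3) and did not pass (adjusted p = 0.394). Nor did acetylcholinesterase Ache (11.2 ± 5.07 against 7.25 ± 1.3 CPM, adjusted p = 0.344). Carry-over of perisynaptic tissue was not tested at this age. The count of 190 was 81 without control replicate 3, 100, 110, 121 and 124 without SBMA replicates 3, 2, 1 and 4, and 518 with DESeq2. With replicate number as a block, which leaves fewer residual degrees of freedom, it was 47, and 23 of 36 named calls were lost. The losses below are those without single animals. Calls were lost for Nr4a1 without control replicate 2 (-1.28) or SBMA replicates 2 and 3 (-1.84 and -1.76), for Cacng1 without control replicate 1 (-0.90) and for Colq without SBMA replicate 3 (1.03). They were also lost for Myh8 without control replicates 1 and 3 or SBMA replicate 1 (0.83 to 0.96), and for Cacna1s without control replicates 2 and 3 or SBMA replicates 2, 3 and 4 (-0.44 to -0.47).

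**Figure D2:**
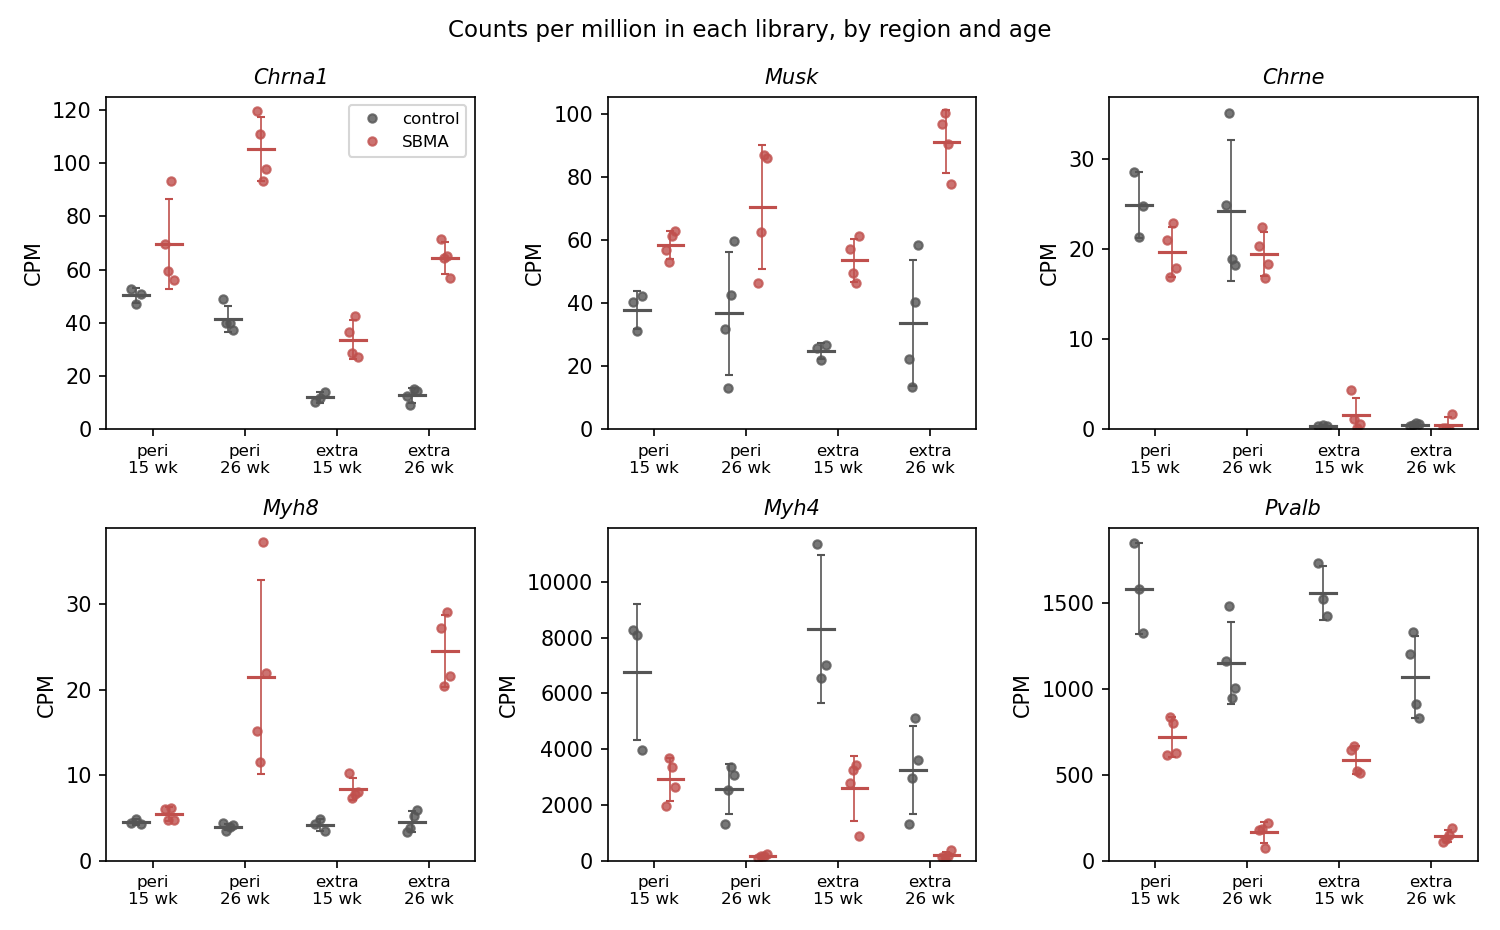
Level (CPM) of 6 genes in each library by region and age (points; lines and bars are the mean and SD of 3 or 4 libraries; control grey, SBMA red; linear axes from 0). Chrna1 measured 64.4 ± 5.99 CPM in extrasynaptic SBMA libraries at 26 weeks against 12.7 ± 2.77 CPM in controls, and Myh4 185 ± 126 (122.5 without SBMA replicate 4) against 3250 ± 1570 CPM.

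By 26 weeks the perisynaptic muscle of SBMA mice had lost most of its transcript of Myh4, and genes of the denervation list were higher as a group. Myh4 (ENSMUSG00000057003.12, chromosome 11, 67238029 to 67260446) fell from 2570 ± 910 CPM (SD, n = 4) to 163 ± 51.1 CPM (SD, n = 4), a log2 fold change of -4.02 ± 0.352 (adjusted p = 3.33e-06), and Pvalb from 1150 ± 240 to 164 ± 62.3 CPM (-2.85 ± 0.27). Nmrk2, a muscle kinase of NAD synthesis, fell from 163 ± 57.6 to 10 ± 3.37 CPM (-4.07 ± 0.315). Prr32 rose from 0.209 ± 0.056 to 7.96 ± 1.91 CPM (5.15 ± 0.331), Igsf1 from 2.46 ± 0.629 to 33.8 ± 7.51 CPM (3.73 ± 0.184) and Chrna1 from 41.4 ± 5.03 to 105 ± 12 CPM (1.31 ± 0.153). In all, 2204 genes passed, 1265 higher and 939 lower, of which 316 and 288 changed by more than 2-fold. With total-count scaling 4642 passed and 91.7% of them were higher, against 57.4% with TMM factors.

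Of 19 genes of the denervation list 6 rose and none fell, 8 and 0 adjusted over the list alone (median 0.61, camera adjusted p = 6.2e-05, 0.0437 with an estimated correlation). They included Ankrd1, a stress-responsive titin-binding protein (3.11 ± 0.52), Myh8 (2.39 ± 0.27) and the cell-adhesion gene Ncam1 (1.35 ± 0.206). Other genes fixed in advance did not pass: the embryonic myosin gene Myh3 (0.16, adjusted p = 0.802), the fetal receptor subunit gene Chrng (0.46, 0.709), the cardiac actin gene Actc1 (0.74, 0.0763) and the transcription factors Myog (0.54, 0.17) and Runx1 (0.59, 0.219). Actc1, Myog and Runx1 passed with total-count scaling (0.98, 0.79 and 0.87), Actc1 also with DESeq2, without the filter on low counts or without SBMA replicate 4 (0.91), and Myog without control replicate 2 (0.81). Among 25 synaptic genes 8 rose and none fell, 11 and 0 adjusted over the list alone (camera adjusted p = 5.36e-05, adjusted p = 0.32 with an estimated correlation), with the beta subunit Chrnb1 at 1.53 ± 0.141 and Colq at 1.01 ± 0.125. The adult epsilon subunit Chrne measured 19.5 ± 2.46 CPM against 24.2 ± 7.84 CPM in controls and did not pass (-0.35 ± 0.19, adjusted p = 0.238), nor did the receptor-clustering kinase gene Musk (0.90 ± 0.31, adjusted p = 0.0668). Of the trophic factors that muscle supplies to motor neurons and vessels, Gdnf (-1.64 ± 0.327), Ntf5 (-0.85 ± 0.179) and Vegfa (-0.75 ± 0.167) fell. These were the 3 of 13 list members that fell over all genes tested, and 3 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.0209, adjusted p = 0.327 with an estimated correlation). Satellite cell genes rose in 5 of 10 cases, 6 with 1 lower adjusted over the list alone (camera adjusted p = 0.00596, adjusted p = 0.342 with an estimated correlation), among them Myf5, a transcription factor of muscle stem cells (0.82 ± 0.165). Some markers of other cell types were lower: 3 of 20 macrophage genes (11 adjusted over the list alone; median -0.51, -0.26 with total-count scaling; camera adjusted p = 0.000318, adjusted p = 0.61 with an estimated correlation), 3 of 14 endothelial genes (3; camera adjusted p = 0.00596, adjusted p = 0.647 with an estimated correlation) and 2 of 12 genes of fibroadipogenic progenitors (2; camera adjusted p = 0.0253, adjusted p = 0.647 with an estimated correlation). Of 12 mesothelial genes none passed (camera adjusted p = 0.0244, adjusted p = 0.663 with an estimated correlation).

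Of 16 fast-fibre genes 15 were lower, and all 16 adjusted over the list alone (median -0.96, camera adjusted p = 3.4e-25, 3.51e-05 with an estimated correlation). They included Myh1 (-1.07 ± 0.181), Myh2 (-1.60 ± 0.197), Myoz1 of the Z disc (-1.08 ± 0.114) and Atp2a1 (-1.16 ± 0.136). Of 12 slow-fibre genes 5 were lower and 1 higher (5 and 1 adjusted over the list alone; camera adjusted p = 0.000545, adjusted p = 0.325 with an estimated correlation). Myh7, the slow myosin, changed by -0.88 ± 0.188 and the troponin gene Tnni1 by -1.43 ± 0.154, while the calsequestrin gene Casq2 rose by 0.84 ± 0.156. Among 64 sarcomere genes 22 were lower and 6 higher, 25 and 10 adjusted over the list alone (camera adjusted p = 7.23e-06, 0.0467 with an estimated correlation). In the calcium list 9 of 47 members fell and 4 rose, 12 and 7 adjusted over the list alone, and the list as a whole was not called (camera adjusted p = 0.116). The fallers included Hrc, which binds calcium in the sarcoplasmic reticulum (-0.68 ± 0.094), Casq1 (-0.54 ± 0.084), Cacng1 (-1.30 ± 0.198) and Cacna1s (-0.76 ± 0.173). Manf (-1.25 ± 0.23) and Sdf2l1 (-1.31 ± 0.184), genes of the endoplasmic reticulum, were lower. Of the unfolded protein response 12 of 29 genes fell and 2 rose, 14 and 3 adjusted over the list alone (camera adjusted p = 4.75e-05, adjusted p = 0.385 with an estimated correlation). When only the 8 libraries compared were fitted, 1302 genes passed and Cacna1s did not (-0.75).

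Extrasynaptic muscle at 26 weeks gave the most calls of the 4 SBMA comparisons, with 5007 of 15526 genes past the threshold, 2502 higher and 2505 lower. Variation between animals was lower there (biological coefficient of variation 0.141 in extrasynaptic and 0.182 in perisynaptic libraries), so the count does not rank the size of the response. With total-count scaling 6286 passed and 84.8% of them were higher, against 50% with TMM factors. Chrna1 rose from 12.7 ± 2.77 CPM (SD, n = 4) to 64.4 ± 5.99 CPM (SD, n = 4), a log2 fold change of 2.30 ± 0.171 (adjusted p = 2.75e-07). Musk rose from 33.7 ± 20 to 91.3 ± 9.88 CPM (1.41 ± 0.285). Chrnb1 rose by 1.86 ± 0.134, Colq by 1.73 ± 0.196 and Etv5, a transcription factor of synaptic nuclei, by 0.86 ± 0.163. Chrne measured 0.512 ± 0.802 CPM in SBMA and 0.508 ± 0.168 CPM in control libraries, but the SBMA mean rests on replicate 4 (1.71 CPM, the others 0.0347 to 0.174 CPM) and was 0.112 CPM without it. The log2 fold change was -0.07 (adjusted p = 0.965) with it and -2.19 without it (adjusted p = 0.139). Of 25 synaptic genes 10 rose and 2 fell, the same numbers adjusted over the list alone (camera adjusted p = 4.53e-05, adjusted p = 0.28 with an estimated correlation). Of 18 denervation genes 6 rose and 2 fell, 9 and 2 adjusted over the list alone (median 0.58, camera adjusted p = 0.0014, adjusted p = 0.28 with an estimated correlation), with Myh8 at 2.38 ± 0.172 and Ncam1 at 1.5 ± 0.185.

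The largest other rises were those of Prr32, from 0.523 ± 0.316 to 9.67 ± 2.95 CPM (4.12 ± 0.347), the neuronal adhesion gene Nrcam (3.77 ± 0.237), Igsf1 (3.71 ± 0.171), the axonal motor protein Kif1a (3.59 ± 0.323) and the keratin gene Krt80 (3.24 ± 0.297). Myh4 fell from 3250 ± 1570 to 185 ± 126 CPM (-4.17 ± 0.533; 122.5 CPM and -4.78 without SBMA replicate 4), Nmrk2 by 4.02, the Wnt antagonist Dkk2 by 4.08 and Pvalb by 2.95. All 16 fast-fibre genes were lower, also adjusted over the list alone (median -1.09, camera adjusted p = 9.9e-31, 0.00124 with an estimated correlation). Of 64 sarcomere genes 28 fell and 14 rose, 30 and 16 adjusted over the list alone (camera adjusted p = 4.33e-05, adjusted p = 0.28 with an estimated correlation). Nuclear-encoded subunits of the respiratory chain and ATP synthase fell in 69 of 78 cases and rose in 1, 72 and 1 adjusted over the list alone (median -0.39, camera adjusted p = 1.96e-18, adjusted p = 0.515 with an estimated correlation). Examples were Uqcrc1 (-0.81 ± 0.079) and Ndufa5 (-0.82 ± 0.093). Genes of fatty acid uptake and oxidation fell in 17 of 30 cases and rose in 1, 18 and 2 adjusted over the list alone (camera adjusted p = 5.33e-06, adjusted p = 0.518 with an estimated correlation), led by the lipoprotein lipase gene Lpl (-1.51 ± 0.092). The chloride channel gene Clcn1, whose loss causes myotonia, changed by -0.42 ± 0.057 and the ryanodine receptor gene Ryr1 by -0.52 ± 0.146. Ryr1 did not pass with total-count scaling (-0.30) or when only the 8 libraries compared were fitted (-0.50).

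Some markers of other cell types moved with genotype in these pieces, less so with total-count scaling. The genes of 13 lists of other cell types, without satellite cells, had a median of -0.374 ± 0.099 (SE over genes) with TMM factors. With total counts it was -0.161 ± 0.099, within 2 such SE of 0. Genes are not independent replicates, and this SE holds no spread between animals. Macrophage genes were lower in 15 of 20 cases, 15 adjusted over the list alone (median -0.66, -0.44 with total-count scaling; camera adjusted p = 3.96e-06, adjusted p = 0.478 with an estimated correlation), with the complement genes C1qa and C1qb at -0.70 ± 0.11 and -0.74 ± 0.11. Endothelial genes were lower in 6 of 14 cases (8 adjusted over the list alone; camera adjusted p = 0.0132, adjusted p = 0.58 with an estimated correlation). Genes of fibroadipogenic progenitors were lower in 7 of 12 (8; camera adjusted p = 0.0168, adjusted p = 0.58 with an estimated correlation). Mesothelial genes were lower in 5 of 12 (7; camera adjusted p = 0.00812, adjusted p = 0.58 with an estimated correlation). Satellite cell genes were higher in 5 and lower in 1 of 10 (7 and 1; camera adjusted p = 0.0372, adjusted p = 0.58 with an estimated correlation). Odc1, the first enzyme of polyamine synthesis, rose by 0.58 ± 0.129, while the kinase gene Mylk4 fell (-1.14 ± 0.263). The hepatocyte gene Alb was 0.26 ± 0.286 CPM in SBMA and 7.17 ± 12 CPM in control libraries. Its log2 fold change was -4.79 ± 1.485, and Alb no longer passed without control replicate 3 (-2.19) or without SBMA replicates 1, 2 or 4 (-4.78, -4.35 and -4.58).

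**Figure D3:**
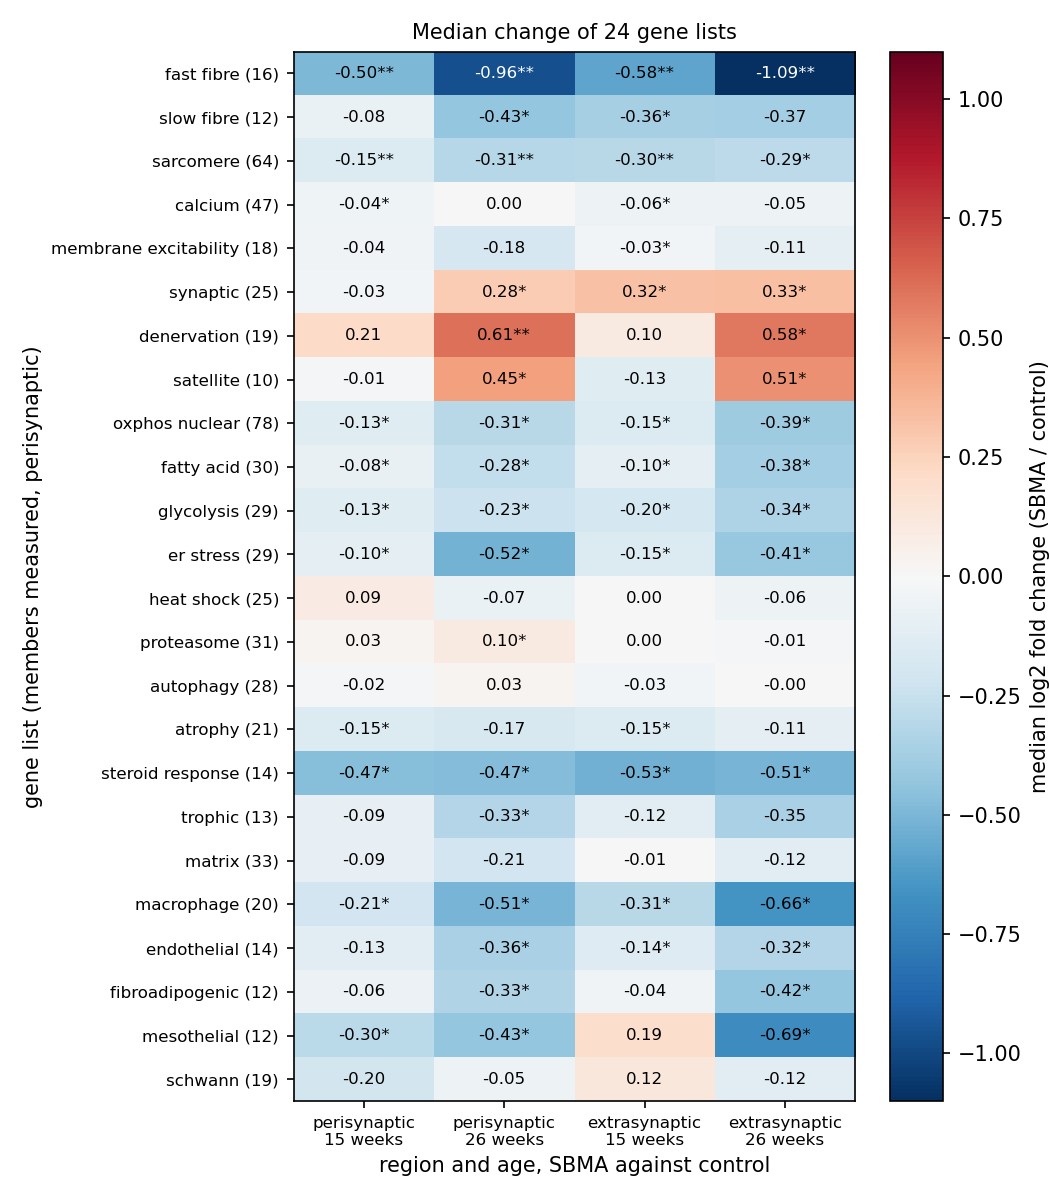
Median log2 fold change of 24 gene lists, SBMA against control, in each region and age (colour and number; rows give the number of members measured in perisynaptic libraries; one star marks a camera adjusted p under 0.05, and a pair of stars marks one that also held with an estimated correlation). Fast-fibre genes were lower in all 4 comparisons (medians -0.50, -0.96, -0.58 and -1.09) and denervation genes higher at 26 weeks (0.61 in perisynaptic and 0.58 in extrasynaptic libraries, where the call did not hold with an estimated correlation), also with total-count scaling; medians nearer 0 than about 0.25 can change sign under that scaling.

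Genes called at 15 weeks mostly pointed the same way at 26 weeks, measured in separate animals. Both ages of a region come from the same fit with shared dispersions, so the lists are not fully independent. Of the 20 perisynaptic genes higher at 15 weeks 19 were also called higher at 26 weeks, against 1.61 for independent lists, and all 13 lower genes were called lower, against 0.776. In extrasynaptic libraries 81 of 86 higher and 100 of 104 lower genes were called again, against 13.9 and 16.8. Across all genes, which are not independent replicates, the log2 fold changes at the 2 ages correlated with r = 0.336 (Spearman's rho 0.509) in perisynaptic and r = 0.543 (rho 0.537) in extrasynaptic libraries, with 70.4% and 71.3% of genes on the same side of 0. Among genes above 2 CPM r was 0.609 and 0.642. The perisynaptic r was 0.175 without control replicate 1 of 15 weeks and 0.506 without control replicate 3 of 26 weeks. Another split of the perisynaptic 15-week animals gave 0.362, above the real 0.336, so chance cannot be excluded for that correlation.

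A direct test of whether the SBMA difference was larger at 26 than at 15 weeks passed for 59 perisynaptic genes, 38 higher and 21 lower, and for 268 extrasynaptic genes, 157 of them higher. With total-count scaling 148 and 247 passed, of which 85.1% and 65.6% were higher, against 64.4% and 58.6% with TMM factors. Nmrk2 declined most in both regions (-3.27 ± 0.427 and -3.13 ± 0.314), followed by the R-spondin receptor gene Lgr6 in extrasynaptic libraries (-2.62 ± 0.465) and by Myh4 in perisynaptic ones (-2.78 ± 0.473). Nrcam gained most in extrasynaptic libraries (3.34 ± 0.35), and it gained 2.06 ± 0.342 in perisynaptic ones. Myh8 gained 2.16 ± 0.393 and 1.43, and Ncam1 1.38 in extrasynaptic libraries. For Chrna1 the gain with age did not pass in either region (0.87 ± 0.222, adjusted p = 0.142; 0.85 ± 0.245, adjusted p = 0.101). As lists, denervation genes gained (5 of 19 higher adjusted over the list alone, 1 over all genes; camera adjusted p = 7.91e-07, 0.0104 with an estimated correlation) in perisynaptic libraries. Fast-fibre genes lost further there (4 of 16 lower adjusted over the list alone, 1 over all genes; camera adjusted p = 1.51e-11, 0.00157 with an estimated correlation). In extrasynaptic libraries the fast-fibre call had an adjusted p = 0.0792 with an estimated correlation (10 of 16 lower adjusted over the list alone, 4 over all genes; camera adjusted p = 8.61e-12). The perisynaptic count was 28, 27 and 32 without control replicates 1 to 3 and 37 without SBMA replicates 2 or 4 of 15 weeks, 39 and 36 without SBMA replicates 1 and 2 and 121 without control replicate 2 of 26 weeks. The extrasynaptic count was 137 without control replicate 2 and 146 and 156 without SBMA replicates 2 and 4 of 15 weeks (lowest without SBMA replicate 1), and 171 without control replicate 1 and 143, 173 and 159 without SBMA replicates 1 to 3 of 26 weeks. DESeq2 called 190 and 649 genes. With replicate number as a block, which leaves fewer residual degrees of freedom, 18 and 29 genes passed. Under that block 6 of 10 perisynaptic and 10 of 15 extrasynaptic named calls were lost. In perisynaptic libraries Myh4 lost its call without control replicate 3 of 15 weeks (-2.51) and Nrcam without control replicates 1 and 2 (2.01 and 1.99). Myh8 lost it without control replicates 1 to 3 or SBMA replicates 2 and 4 of 15 weeks or control replicate 3 of 26 weeks (2.09 to 2.19). In extrasynaptic libraries Ncam1 lost its call without control replicate 2 of 15 weeks (1.22).

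Averaged over the genotypes, older diaphragm had higher heat shock transcripts and less fast myosin, and in perisynaptic libraries Myh4 fell more in SBMA. Of 15735 perisynaptic genes 324 differed between 26 and 15 weeks, 160 higher and 164 lower, and of 15526 extrasynaptic genes 738, 397 higher and 341 lower. With total-count scaling 334 and 1527 differed, of which 69.2% and 85.5% were higher, against 49.4% and 53.8% with TMM factors. The inducible heat shock genes Hspa1a and Hspa1b, near-identical copies whose reads may be split, rose by 1.81 ± 0.4 and 2.00 ± 0.423 in perisynaptic and by 1.89 ± 0.346 and 2.07 ± 0.402 in extrasynaptic libraries, and Hsp90aa1 by 1.31 ± 0.177 in the latter. Of 25 heat shock genes 13 rose and 1 fell in extrasynaptic libraries, 16 and 1 adjusted over the list alone (camera adjusted p = 2.14e-15, 0.0494 with an estimated correlation). In perisynaptic ones 7 rose and 1 fell, 13 and 1 adjusted over the list alone (camera adjusted p = 4.32e-10, adjusted p = 0.11 with an estimated correlation). Myh4 was lower at 26 weeks in both regions (-2.80 ± 0.24 and -2.60 ± 0.358), as were 8 of 16 fast-fibre genes in each (9 and 14 adjusted over the list alone; camera adjusted p = 1.94e-17 and 8.38e-20, 0.000373 and 0.0109 with an estimated correlation). In perisynaptic libraries Myh4 went from 6780 ± 2440 (SD, n = 3) to 2570 ± 910 CPM (SD, n = 4) in control and from 2910 ± 773 to 163 ± 51.1 CPM (SD, n = 4 each) in SBMA animals, and the genotype by age difference was -2.78 ± 0.473 (adjusted p = 0.0169), a call lost without control replicate 3 of 15 weeks (-2.51). In extrasynaptic libraries it was -2.44 ± 0.707 (adjusted p = 0.1) and passed with DESeq2 (-2.44), without the filter on low counts (-2.46) or without SBMA replicate 4 of 26 weeks (-3.06). The mean of the fast-fibre list also fell more in SBMA. On a log2 scale centred over all libraries it went from 0.596 to 0.378 in control and from 0.041 to -0.835 in SBMA perisynaptic libraries. In extrasynaptic ones it went from 0.637 to 0.418 and from -0.049 to -0.877. Of 64 sarcomere genes 9 were lower and 1 higher in perisynaptic libraries, 12 and 3 adjusted over the list alone (median -0.13, camera adjusted p = 2.59e-07, 0.0378 with an estimated correlation). Of 18 membrane excitability genes 5 were lower and 1 higher in extrasynaptic libraries, the same numbers adjusted over the list alone (median -0.16, camera adjusted p = 0.00122, 0.0494 with an estimated correlation). Collagens and other matrix genes were lower in 8 of 33 cases in extrasynaptic libraries (17 with 1 higher adjusted over the list alone; camera adjusted p = 2.23e-10, adjusted p = 0.375 with an estimated correlation). Age coincides with the runs of animal numbers and may coincide with other unrecorded differences between the collections. The perisynaptic count was 166 without control replicate 1 of 15 weeks, 206 and 211 without SBMA replicates 1 and 2 and 528 without control replicate 2 of 26 weeks. The extrasynaptic count was 459 without control replicate 1 and 467 and 451 without SBMA replicates 1 and 2 of 15 weeks, 458 and 473 without SBMA replicates 2 and 3 and 1181 without control replicate 2 of 26 weeks. DESeq2 called 693 and 1290 genes. With replicate number as a block, which leaves fewer residual degrees of freedom, 251 extrasynaptic genes passed. In perisynaptic libraries Hspa1b lost its call without control replicates 1 or 3 of 15 weeks (1.98 and 1.94) and Hspa1a without several single animals (1.54 to 1.86).

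Within animals, the perisynaptic piece differed from the extrasynaptic one in the genes of synaptic nuclei and of nerve. In 7 control animals Chrne, the adult receptor subunit gene (ENSMUSG00000014609.16, chromosome 11, 70614883 to 70619216), measured 24.5 ± 5.93 CPM (SD, n = 7) perisynaptically and 0.449 ± 0.149 CPM extrasynaptically, a log2 difference of 5.78 ± 0.441 (adjusted p = 1.95e-07), with the same direction in all 7 animals. B4galnt3, a glycosyltransferase gene, measured 5.42 ± 1.99 and 0.0633 ± 0.0556 CPM (6.38 ± 0.422). In total 460 of 16138 genes differed in controls, 339 higher and 121 lower perisynaptically. Of 25 synaptic genes 15 were higher (19 adjusted over the list alone; camera adjusted p = 1.33e-124, 1e-05 with an estimated correlation). Among them were the delta subunit Chrnd at 4.25 ± 0.267, acetylcholinesterase Ache at 3.32 ± 0.195, the transcription factors Etv4 and Etv5 at 4.35 ± 0.269 and 2.76 ± 0.091, and Chrna1 at 1.90 ± 0.083. Of 19 Schwann cell genes 17 were higher, also adjusted over the list alone (camera adjusted p = 4.68e-69, 0.00129 with an estimated correlation), and the trophic factor gene Gdnf stood at 5.86 ± 0.421. Adipocyte genes were lower in 6 of 9 cases (8 adjusted over the list alone; camera adjusted p = 8.69e-09, adjusted p = 0.264 with an estimated correlation), for example Adipoq (-2.71 ± 0.667). Genes of tendon and its junction were lower in 3 of 12 (3 adjusted over the list alone; camera adjusted p = 0.00187, adjusted p = 0.542 with an estimated correlation), among them Col22a1 (-2.50 ± 0.368), while the list median of -0.02 turned to 0.04 with total-count scaling. The count was 261 without control replicate 1 of the 15-week animals, 269 without the animal as a block and 1095 without the filter on low counts. Adipoq lost its call without control replicates 1 to 3 of 15 weeks or 3 and 4 of 26 weeks (-2.27 to -3.08).

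The same regional genes stood out in 8 SBMA animals, where 570 genes differed, 452 of them higher perisynaptically. Of the 339 genes higher in controls 256 were called higher in SBMA, against 9.49 for independent lists, and of the 121 lower genes 35 were called lower, against 0.885. Chrne measured 19.5 ± 2.41 CPM (SD, n = 8) and 1.03 ± 1.48 CPM (4.61 ± 0.367), and B4galnt3 2.63 ± 0.893 and 0.128 ± 0.186 CPM (4.86 ± 0.405). Extrasynaptic replicate 1 of 15 weeks held 4.39 CPM of Chrne (others 0.0347 to 1.71) and 0.539 CPM of B4galnt3 (others 0 to 0.218). Without that library the means were 0.551 and 0.0692 CPM. Without that animal the log2 differences were 5.18 and 5.33, and without replicate 4 of 26 weeks 5.65 and 6.13. Chrna1 measured 87.5 ± 23.4 and 49 ± 17.6 CPM, a log2 difference of 0.88 ± 0.07. Of 25 synaptic genes 12 were higher (18 adjusted over the list alone; camera adjusted p = 1.88e-69, 0.000213 with an estimated correlation), and of 19 Schwann cell genes 17 (18; camera adjusted p = 3.67e-65, 0.0012 with an estimated correlation). Without SBMA replicate 4 of the 26-week animals 1341 genes passed. Without replicates 1 or 2 at that age 330 and 329 passed, without replicates 3 or 2 at 15 weeks 324 and 366, and without the animal as a block 267; without the filter on low counts 1795 passed.

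**Figure D4:**
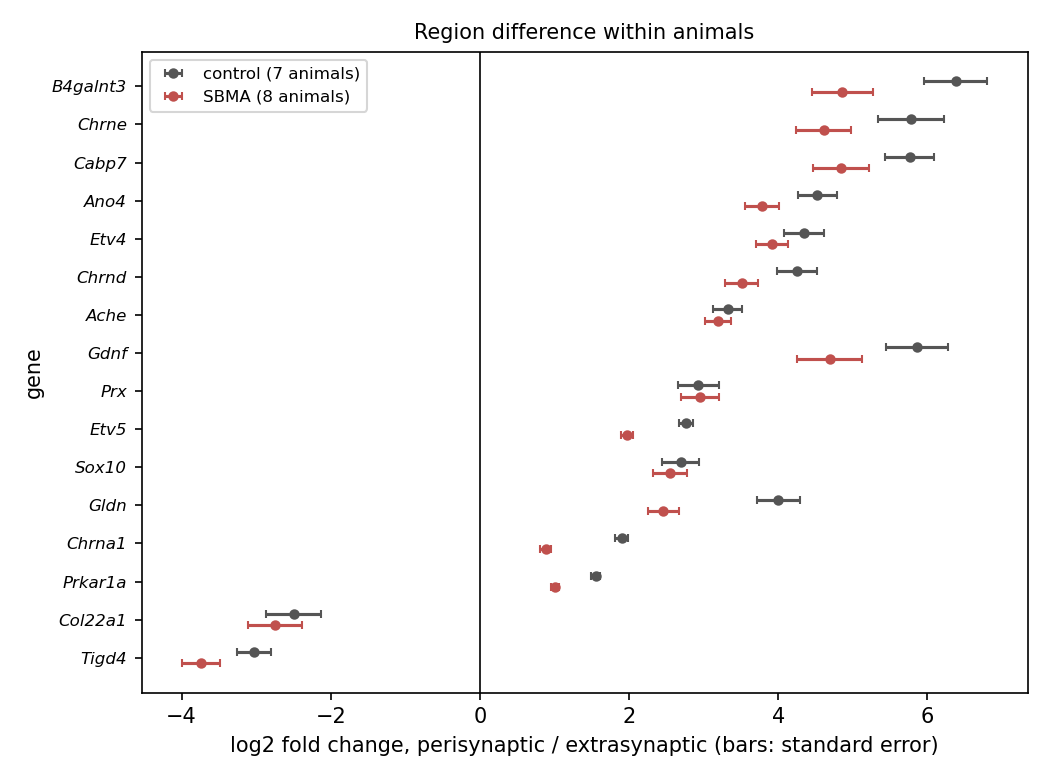
Log2 fold change between perisynaptic and extrasynaptic libraries of the same animals for 16 genes (points; bars are the SE; grey, 7 control animals; red, 8 SBMA animals; values above 0 are higher perisynaptically). The difference of Chrna1 was 1.90 ± 0.083 in control and 0.88 ± 0.07 in SBMA animals, and that of Chrne 5.78 ± 0.441 and 4.61 ± 0.367.

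Whether the regional difference itself depended on genotype was tested within animals at each age. At 26 weeks 2 genes passed. For Chrna1 the perisynaptic excess was smaller in SBMA than in control animals by a log2 difference of -1.01 ± 0.145 (adjusted p = 0.0212). The call for Chrna1 was lost with total-count scaling (-0.95), without the animal as a block (-1), when only the 8 animals of that age were fitted (-1.02). It was also lost without control replicate 1 (-0.93) or any of SBMA replicates 1 to 4 (-0.96 to -1.04), while the size stayed close to the same. The other gene, the immunoglobulin segment Igkv14-126, had counts in a few perisynaptic SBMA libraries, so no fold is given. At 15 weeks no gene passed with edgeR, and DESeq2 called 5. An unadjusted edgeR p under 0.05 was found for 421 of 16138 genes, fewer than the 5% that chance alone would give. Chrna1 stood at -1.02 ± 0.16 at this age (adjusted p = 0.117). Camera called a smaller regional difference of the synaptic list in SBMA at each age, but neither call held with an estimated correlation or with fry. At 15 weeks 0 of 25 genes passed over all genes and 5 were lower adjusted over the list alone (camera adjusted p = 4.35e-17, adjusted p = 0.0743 with an estimated correlation and 0.359 with fry). At 26 weeks 1 was lower over all genes, and 8 were lower and 1 higher adjusted over the list alone (camera adjusted p = 9.83e-07, adjusted p = 0.995 with an estimated correlation and 0.994 with fry).

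Over all comparisons, camera called 178 of 440 tests of a list in a comparison, and 19 held with an estimated correlation. Those that held were fast-fibre genes in the 4 SBMA comparisons, in the age by genotype test of perisynaptic libraries and in both age comparisons. Sarcomere genes held in SBMA at 15 weeks in both regions and at 26 weeks in perisynaptic libraries, and with age in perisynaptic libraries. Denervation genes did so at 26 weeks and in the age by genotype test in perisynaptic libraries. The others were heat shock and membrane excitability genes with age in extrasynaptic libraries, and synaptic and Schwann cell genes between the regions in both genotypes.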

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

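The tests of other tissue in 1 piece, of carry-over between the pieces, of scaling, of a denervation response and of the share of muscle RNA were chosen after the results had been seen; the tests of transcript length and GC and the counts of other splits were planned.

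In groups of 4 to 8 libraries, 80 sets of values were searched for a library far from the others by Dixon's test, and 7 had one; chance gives about 1 in 20. The extrasynaptic control replicate 4 at 26 weeks had a total count of 34694446, against 21980000 to 23380000 in the other 3, and 0.139% of counts on ribosomal RNA-like features, against 0.0423% to 0.0568%. In extrasynaptic SBMA libraries at 26 weeks replicate 4 had 371 CPM of Myh4 (others 108 to 150) and 1.71 CPM of Chrne (others 0.0347 to 0.174). In extrasynaptic control libraries at 26 weeks replicate 3 had 25 CPM of Alb (others 0.132 to 2.87). Over both ages, extrasynaptic SBMA replicate 1 of 15 weeks had 4.39 CPM of Chrne (others 0.0347 to 1.71) and 0.539 CPM of B4galnt3 (others 0 to 0.218), and both genes are high in perisynaptic pieces.

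The SBMA difference itself differed between the ages for 59 perisynaptic and 268 extrasynaptic genes, by a test of the difference. In perisynaptic libraries the values were 2.19 for Krt80, 2.16 for Myh8, 2.06 for Nrcam, 1.89 for Aif1l and 1.58 for Bex1, and -3.27 for Nmrk2, -2.78 for Myh4, -2.62 for Lgr6, -2.14 for Adig and -2.12 for Gnmt. In extrasynaptic libraries they were 3.34 for Nrcam, 2.47 for Kif1a, 2.27 for Krt80, 2.22 for Traf3ip3, 2.18 for Aif1l, 1.43 for Myh8 and 1.38 for Ncam1. The negative ones there were -3.13 for Nmrk2, -2.62 for Lgr6, -2.39 for Zfp750, -2.39 for Wnt16, -2 for Unc13c, -1.49 for Pvalb, -1.08 for Myh2 and -0.41 for Clcn1. Between the regions the SBMA difference at 26 weeks differed for 2 genes, Chrna1 (-1.01) and Igkv14-126.

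The perisynaptic control library of replicate 2 at 26 weeks lay apart from the other 3 of its group. The SD over genes of its log2 deviation was 0.685, against 0.345, 0.486 and 0.479. Other tissue picked up in that piece alone cannot be told apart: the deviations of the 2 pieces of this animal correlated across genes with r = 0.615, but those of the other 3 control animals also did (0.358, 0.526 and 0.533), so the value does not decide. Transcript length and GC content explained 22.8% of the variance of the deviation, the largest value among the 16 libraries of that age. A length or GC bias may therefore be part of the difference, and it was not confined to that library. Spearman's rho of the perisynaptic deviation with transcript length was -0.412 there, and 0.0184, -0.35 and -0.317 in control replicate 1 and SBMA replicates 1 and 2 of the same run. In the other run it was 0.385 and 0.311 in control and 0.311 and 0.355 in SBMA libraries. Deviations are taken from the rest of a group, so signs within a group are not independent. What lies behind the remainder stays open. No biological explanation was tested.

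Chrna1 was higher in extrasynaptic SBMA libraries at 26 weeks. If perisynaptic tissue in those pieces were the source, a share of 55.8% would be needed, while 14 genes over 8-fold higher in perisynaptic control libraries reached a median of 4.08% of their perisynaptic SBMA level (quartiles 2.63% and 7.85%), and none reached the needed share. Scaling of the libraries is not the source either, since with total counts the log2 fold change was 2.52 in place of 2.30. A denervation response of the fibres may underlie the rise but stays open: the denervation list, which holds Chrna1, had an adjusted p = 0.28 with an estimated correlation.

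Fast-fibre genes were lower in SBMA at 26 weeks. A trend on transcript length and GC is not the whole cause, since its removal left list medians of -0.83 in perisynaptic and -0.92 in extrasynaptic libraries, against -0.96 and -1.095. Scaling is not the whole cause in extrasynaptic libraries (-0.887 with total counts). In perisynaptic libraries the median of -0.71 was just short of the bound of 0.75 of the TMM value set for excluding it, so part of the fall there may come from scaling, though all 16 members stayed lower. A lower share of muscle fibre RNA would lower all fibre genes alike, and list means (± SD, n = 4, log2 scale centred over all libraries) argue against it as the whole cause. From control to SBMA extrasynaptic libraries the fast-fibre mean went from 0.418 ± 0.058 to -0.877 ± 0.105. The sarcomere mean, which shares members with it, went from 0.084 ± 0.096 to -0.221 ± 0.087. In perisynaptic ones the fast-fibre mean went from 0.378 ± 0.082 to -0.835 ± 0.078 and the calcium mean from -0.013 ± 0.188 to -0.135 ± 0.057. A lower share as part of the fall cannot be told apart. Such a shift would raise genes of other cell types, and those of 13 lists had medians of -0.36 ± 0.105 and -0.374 ± 0.099 with TMM factors. With total counts the medians were -0.094 ± 0.104 and -0.161 ± 0.099, within 2 SE of 0. The SE here is over genes, which are not independent replicates, and holds no spread between animals. A change of fibre type with genotype was not tested apart from these explanations.

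Chance assignment of animals can be excluded for most counts, where 1 of the splits, the real one, gave as many calls. This holds for the SBMA comparisons at 15 weeks (33 perisynaptic and 190 extrasynaptic calls, highest of the other 34 splits 1 and 1) and in extrasynaptic libraries at 26 weeks (5007, highest other 3 of 35 splits). At 15 weeks genotype is not balanced over the runs of animal numbers, so these splits do not separate genotype from the runs. By this count chance was also excluded for age (324 and 738 calls, highest of 100 splits otherwise 209 and 669). The same held for the regions in control and SBMA animals (460 and 570, highest of 64 splits otherwise 3 and 25). Splits for age, for genotype by age and for the regions in SBMA animals were a random sample of those possible. The age splits with 209 and 669 calls kept the ages of all SBMA animals and so part of the age difference. Age coincides with the runs of animal numbers, so these splits cannot separate the 2. For genotype by age 4 of 100 splits gave as many in each region (59 and 268 calls), a share under 0.05. Each split also reassigns the SBMA difference shared by the ages, so this count does not decide on chance. The highest others, 1364 and 3885, kept the genotypes at 26 weeks and exchanged most of them at 15 weeks. This points to a structure of the samples: 97.7% to 100% of the genes called at 15 weeks had the same direction at 26 weeks, and such a split turns an SBMA difference shared by the ages into one between them, so it is no measure of chance.

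For SBMA against control in perisynaptic libraries at 26 weeks 2 of 35 splits gave as many calls, so chance cannot be excluded by this count. The real split gave 2204 and the other 2231. That other split sets the 2 runs of animal numbers against each other, which points to a difference between the runs. Trends of the deviations on transcript length also had opposite signs in most perisynaptic libraries of the 2 runs. Genotype is balanced over the runs, the comparison with the run as a block called 3222 genes, and within the runs 1107 and 797 were called. A pairing of these animals by replicate number cannot be told apart from the runs. The 8 splits that part every same-number pair are too few for a share under 0.05 (real 2204 calls, highest other 0). For genotype by region at 26 weeks 4 of 35 splits gave at least the 2 real calls, so chance cannot be excluded, and the split along the runs gave 1801. At 15 weeks the real count was 0, so all 35 splits gave as many, and the highest other gave 13. The correlation between the ages was as large as the real 0.336 in 2 of 35 splits of the perisynaptic 15-week animals (highest other 0.362), so chance cannot be excluded. In extrasynaptic libraries it was so in 1 of 35, the real one (0.543, highest other 0.387), so it can.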

How the results depend on the processing

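Scaling by total counts was chosen after the data had been seen; all other alternatives were planned. RLE factors left each count of genes within 1.5 times its value, and no call of a named gene reversed under any alternative. The cause was not tested for the changes below unless named.

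DESeq2 called 129 genes (SBMA, perisynaptic, 15 weeks), 518 (SBMA, extrasynaptic, 15 weeks), 190 and 649 (genotype by age, perisynaptic and extrasynaptic), 693 and 1290 (age), and 5 for genotype by region at each age. Without the filter on low counts the counts were 68 and 291 (SBMA at 15 weeks), 1095 and 1795 (region, control and SBMA), and 154 and 65 (genotype by region, 15 and 26 weeks). With total counts they were 4642 (SBMA, perisynaptic, 26 weeks), 2356 (SBMA, extrasynaptic, 15 weeks), 148 (genotype by age, perisynaptic), 1527 (age, extrasynaptic) and 1 (genotype by region, 26 weeks). With replicate number as a block, which leaves fewer residual degrees of freedom, they were 10 and 47 (SBMA at 15 weeks), 18 and 29 (genotype by age) and 251 (age, extrasynaptic). With the run of animal numbers as a block genotype by age called 93 perisynaptic genes. With only the groups compared, and so fewer samples, 1302 genes were called (SBMA, perisynaptic, 26 weeks), and for genotype by region 2 at 15 and 0 at 26 weeks. Without the animal term the region counts were 269 and 267 and that for genotype by region at 26 weeks was 0 with edgeR (2 with the animal term). Of 440 list tests 178 had a camera call, 19 with an estimated correlation and 75 with fry. Among genes above 2 CPM the correlation between the ages was 0.642 in extrasynaptic libraries.

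Leaving out 1 animal, which leaves fewer samples, gave 6 to 20 perisynaptic and 81 to 189 extrasynaptic calls for SBMA at 15 weeks, and 1602 to 2706 and 3972 to 5139 at 26 weeks. Genotype by age gave 27 to 121 and 1.2e+02 to 342, age 166 to 528 and 451 to 1181, region 261 to 387 in control and 324 to 1341 in SBMA, and genotype by region 0 to 6 and 0 to 3. The correlation between the ages was 0.175 to 0.506 and 0.465 to 0.558. Single named genes lost their call under at least 1 alternative other than a left-out animal in 10 of 15, 25 of 36, 38 of 107 and 29 of 137 cases (SBMA at 15 weeks perisynaptic and extrasynaptic, then at 26 weeks). Depth limits genes near 0 CPM, such as Chrne and Alb in extrasynaptic libraries.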
